A study of Mus musculus with 12 samples.

How the data were processed

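RNA was sequenced from in vitro differentiated cardiomyocytes of the murine embryonic stem cell line CM7/1, in versions carrying an inducible Hey1 or Hey2 gene. The labels name 4 RNA libraries, 1 for each combination of line (Hey1 or Hey2) and doxycycline treatment. Induced cells had received 1000 ng/ml doxycycline for 48 h, and uninduced cells are the controls. Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy kit and libraries were made with NEBNext reagents. The series also lists 8 chromatin immunoprecipitation samples, which were not analysed here.

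The values are RPKM (reads per kilobase of gene model, scaled to library depth) that the authors deposited in a table of 23427 genes, per the file headers, with 1 column for each of the 4 libraries. The same table holds a signed fold for each line, a score the authors computed from their RPKM: the ratio of induced to uninduced where that ratio is at least 1, and otherwise minus its inverse. Reads were aligned to the mouse build mm9, and Bowtie 1.0, DESeq (version not given in the sources used here) and MACS 1.4.1 are named, per the submitters' processing notes, which assign no tool to a step. The gene annotation, the read counter, strand handling and the treatment of reads with several matches are not given in the sources used here. Genes were named by the symbols in the table. For the 1966 rows without a symbol, the NCBI RefSeq gene table of GRCm38.p6 was used for names only. Of the Entrez identifiers, 23334 matched that table. Its coordinates belong to another build than mm9, so none are given.

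The table has blank cells and no zeros. The depth behind the values was recovered from their steps, because within a line each ratio of values is a ratio of whole reads times 1 fixed depth ratio. Of 15371 genes with a value, 15363 (99.9%) gave whole reads in every listed library at a whole-base gene length of up to 25000 bases, with a largest allowed deviation of 3e-06 reads. With 1 depth set wrong by 1%, 1.8% of genes did. On simulated values, the exact reads came back for 96.2% of 2986 genes. The lengths of 620 genes were raised to a multiple so that no read number fell below the smallest listed one. The recovered divisors were 7.4 and 7.5 M reads for the uninduced and induced Hey1-line libraries, and 5.75 and 10.375 M for those of the Hey2 line. Listed values start at about 10 reads in the Hey1 line and at about 5 in the Hey2 line, a floor read off the recovered reads. At the smallest possible lengths, 30 and 40 of 11684 genes lay under it in the uninduced and induced Hey1-line libraries, and 12 and 2 in those of the Hey2 line. A blank cell was therefore taken as fewer reads than this floor and not as a zero.

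Differences are of log2(RPKM + 1), induced minus uninduced or Hey2 line minus Hey1 line, and this pseudocount of 1 RPKM understates the change of genes with low values. Folds are ratios of the RPKM themselves, with an exact 95% interval (conditional binomial) from the recovered reads. A single library's RPKM has an exact Poisson interval. PCR copies of a molecule are not independent, so all intervals and floors cover counting error only. A gene was compared when it had a value in all 4 libraries and a mean of at least 1 RPKM over them, which left 10991 genes. Another 695 genes with 4 values lay under that mean and 6 entries were exact copies of another. The demand for 4 values was added after blank cells were seen, because no difference can be computed against a blank. Genes with a near-identical copy, such as ribosomal protein genes with pseudogenes, overlapping genes and antisense genes are uncertain, since it is not given how their reads were assigned.

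With 1 library per group no difference has a replicate check. Genes were therefore counted by size, as differences of at least 2-fold on the log2(RPKM + 1) scale, without p-values. Read sets with equal expression in both libraries were simulated 200 times to show how many genes pass this size from counting error alone. For each of 33 gene lists the median difference of the compared members was set against 10000 random lists of the same size, matched on mean expression in 10 bins, for lists with at least 5 compared members. Percentiles below 2.5 or above 97.5 are called outside the range of random lists, and describe these libraries only. The single test across libraries used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) with line and induction as terms, moderated variances with a trend, two-sided p-values and Benjamini-Hochberg adjustment. In it the 2 lines stand for replicates of induction, so the p-values are for the mean difference over the 2 inductions, and only the difference between them supplies the residual variance, with 1 degree of freedom. Other steps ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and plots in Matplotlib 3.10.9.

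The groups, comparisons, size rule, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. By that rule the named genes are Hey1 and Hey2, the 10 highest and 10 lowest differences in each line, up to 10 genes per direction past 2-fold in the same direction in both lines, list members past 2-fold with up to 4 examples per list and line by size of the difference, the 2 members with the highest mean RPKM of a list that is discussed, the 5 highest and 5 lowest differences between the inductions, and up to 10 limma calls by p-value. The rule did not cover the difference between lines, where the same choice of genes was made after the data were seen. Any other gene is named as chosen after its values were seen. Small RNAs and genes without a known function were counted and mostly not named.

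The lists were Notch pathway and Hes/Hey, sarcomere, cardiac transcription factors, calcium handling and ion channels, atrial-associated, ventricular-associated, pluripotency, mesoderm and cardiac progenitor, endothelial, smooth muscle, fibroblast and extracellular matrix, epicardial, endoderm, neural, blood, skeletal muscle, TGF-beta and BMP, epithelial-mesenchymal transition, Wnt and Fgf, cell cycle, p53 targets, integrated stress response, mitochondrially encoded, nuclear-encoded oxidative phosphorylation, fatty acid oxidation, glycolysis, hypoxia, immediate early, heat shock and unfolded protein, cholesterol synthesis, interferon response, housekeeping reference, and RNA type and quality markers. Some genes stand in more than 1 list, for example Myl4 and Myl7 in the sarcomere and atrial lists. Several epicardial members (Krt8, Krt18, Krt19) are keratins of simple epithelia in general.

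Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter or a mean of at least 5 RPKM, median ratio and upper quartile scaling of the libraries, size rules of 1.5-fold and 3-fold, the other line's uninduced library as control, the mean in place of the list median, and limma without the line term, without the trend or with each library left out. Added after the data were seen were blank cells set to 0, at least 50 reads in each library, random lists matched on gene length, removal of a length trend, and genes listed in both libraries of 1 line.

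The steps were tested on simulated reads of 10987 genes, of which 200 were changed by known folds, with added spread between libraries. In the simulated Hey1 induction the 2-fold size rule found 19.4% of 98 genes with a true 2-fold change and 87.3% of 102 with a 4-fold change, and it passed 5 of 10787 unchanged genes. In the simulated Hey2 induction the shares were 21.4% and 93.1%, with 2 unchanged genes. With the Hey1-induction differences shuffled among genes, 3% of 100 random lists of 20 genes lay outside the percentile limits, and 100% of lists raised by 0.25 lay above the upper one. For common induction limma found 89.8% of the 98 genes with a 2-fold change and 100% of those with a 4-fold change, but 20 of its 210 calls (9.52%) were unchanged genes, more than the nominal 5%.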

Results

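RNA-seq was carried out on cardiomyocytes differentiated in vitro from the murine embryonic stem cell line CM7/1. Hey1 and Hey2 are transcriptional repressors of the hairy and enhancer-of-split family that act downstream of Notch, and each line carried 1 of them under doxycycline control. The 4 libraries were uninduced and induced cells of the Hey1 line and uninduced and induced cells of the Hey2 line, with 1 library in each group. The libraries held 3151820, 3142909, 2296861 and 4183290 reads in listed genes, in that order, with a median of 99, 95, 74 and 117 reads per listed gene. A value was given for 12311, 12198, 14177 and 15095 genes. The 10 most abundant genes took 11.5% and 12.9% of these reads in the uninduced and induced Hey1-line libraries, and 3.34% and 3.20% in those of the Hey2 line. There were no replicates, so every fold is a ratio of 2 libraries with a 95% interval of counting error only, and no group has a second library to show its spread between cultures. No RNA library came from doxycycline-treated cells without an inducible Hey gene, so every difference with induction may hold an effect of the drug.

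Each induced gene was higher in the induced library of its own line. Hey1 (Entrez 15213) stood at 0.735 RPKM (0.380 to 1.28) in uninduced and 8.59 RPKM (7.23 to 10.1) in induced Hey1-line cells. This was 11.7-fold higher (6.48 to 23.1), from 12 and 142 reads. Hey2 (Entrez 15214) had no listed value in uninduced Hey2-line cells, where the floor of 5 reads equals 0.343 RPKM, and stood at 6.59 RPKM (5.64 to 7.64) after induction, from 173 reads, at least 19.2-fold higher. In the Hey2 line Hey1 was 2.46-fold lower after induction (1.06 to 5.92), at 1.18 and 0.481 RPKM from 15 and 11 reads. In the Hey1 line Hey2 stood at 0.694 and 0.895 RPKM from 13 and 17 reads, a ratio of 1.29 that lay within counting error (0.590 to 2.89). Both induced genes were thus highest in the library whose label names them. The values do not separate the transgene from the resident gene.

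**Figure D1:**
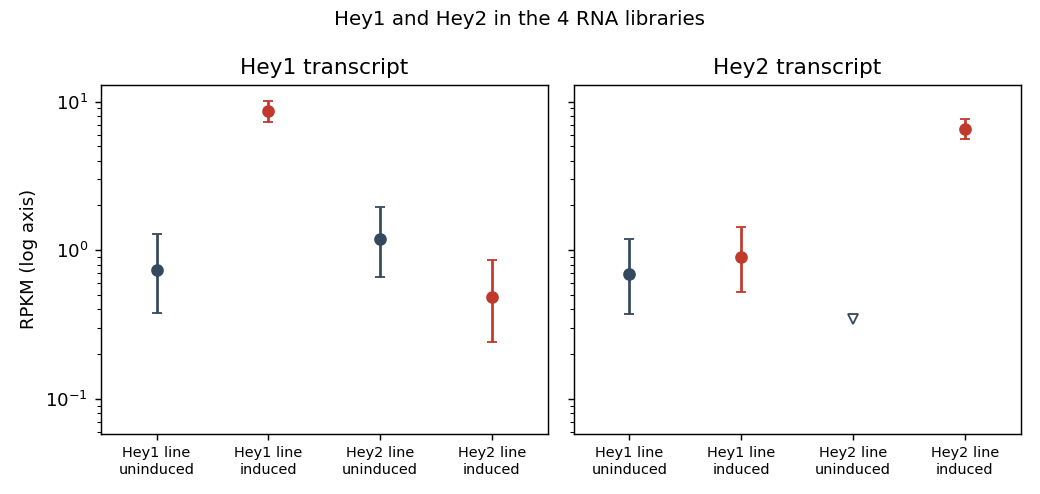
RPKM of Hey1 and Hey2 on a log axis in each of the 4 libraries, with 95% Poisson intervals as bars and the 5-read listing floor of Hey2 in uninduced Hey2-line cells as an open triangle. Hey1 reached 8.59 RPKM only in the induced Hey1 line and Hey2 reached 6.59 RPKM only in the induced Hey2 line.

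The next question was which genes differed when Hey1 was induced. Next to Hey1 itself, the immediate early transcription factor Egr1 was higher after induction, at 5.37 and 14.5 RPKM, 2.70-fold (2.19 to 3.35). Egln3, an oxygen-sensing prolyl hydroxylase whose gene is itself induced by hypoxia, was 3.48-fold lower (2.16 to 5.81), at 3.99 and 1.15 RPKM. Ddit4, an inhibitor of mTORC1 signalling, was 2.20-fold lower (1.80 to 2.69), at 25.6 and 11.6 RPKM. Hypoxia and cell cycle genes were lower as groups, and immediate early genes were higher.

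Of 15 hypoxia genes compared, 14 were lower in the induced Hey1-line library, with a median difference of −0.30 on the log2 scale, at percentile 0.07 of random lists (95% range −0.20 to 0.06). RNA type and quality markers were lower in the same comparison (median −0.26, 7 of 9 lower). Besides Egln3, the mitophagy receptor Bnip3 was 1.95-fold lower (1.45 to 2.66) and the vasodilator peptide gene Adm 1.56-fold lower (1.17 to 2.09). The pyruvate dehydrogenase kinase gene Pdk1 was 1.38-fold lower (1.20 to 1.58). The haem-degrading enzyme gene Hmox1 was the exception, 1.23-fold higher (1.10 to 1.36). Of 29 cell cycle genes 25 were lower, with a median of −0.23 at percentile 0.03. Cyclin B2 (Ccnb2) was 1.99-fold lower (1.23 to 3.29), E2f1 1.74-fold lower (1.18 to 2.60) and cyclin B1 (Ccnb1) 1.74-fold lower (1.04 to 2.98). Mcm3 lay 1.19-fold lower, within counting error (0.987 to 1.43).

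Of 15 immediate early genes 10 were higher in the induced Hey1-line library, with a median of 0.17 at percentile 99.96. Fos was 2.55-fold higher (1.27 to 5.45), Zfp36 1.46-fold (1.09 to 1.97) and Ier2 1.41-fold (1.07 to 1.86). Sarcomere genes had a median of only 0.04, yet at percentile 99.1, because the median of all genes was −0.06. Of 27 sarcomere genes 17 were higher, led by Myom2 at 1.36-fold (1.26 to 1.47), Tnni3 at 1.27-fold (1.21 to 1.33) and Myh6 at 1.24-fold (1.22 to 1.248), while Myl4 stood at 1.02-fold lower. Of 21 cardiac transcription factor genes 15 were higher (median 0.07, percentile 99.2), among them Tbx2 at 1.24-fold (1.04 to 1.47) and Srf at 1.21-fold (1.08 to 1.36), with Ankrd1 1.15-fold lower (1.12 to 1.18). Of 22 TGF-beta and BMP genes 14 were higher (median 0.07, percentile 99.3), with the inhibitor Id2 1.30-fold higher (1.06 to 1.59) and Skil, a repressor of Smad signalling, 1.55-fold lower (1.23 to 1.97). The RNA type and quality markers lay at percentile 1.67. Their ribosomal protein genes Rpl3, 1.5-fold lower (1.17 to 1.93), and Rplp1, 1.30-fold lower (1.14 to 1.48), have pseudogene copies and are uncertain.

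In all, 15 of 10991 genes (0.136%) differed by 2-fold or more on the log2(RPKM + 1) scale in the Hey1 line, 3 higher and 12 lower. Read sets with equal expression gave a mean of 2.36 such genes (0 to 6). The third higher gene was Wdr38, 2.65-fold (1.54 to 4.75). Lower ones included C1d, a nuclear exosome cofactor, 3.09-fold (2.16 to 4.51), the replication gene Gins1, 2.38-fold (1.58 to 3.67), Cyp3a13, 2.56-fold (1.79 to 3.71), and Hddc2, 2.46-fold (1.29 to 4.96). Rps27a, a ribosomal protein gene with pseudogenes, was 2.22-fold lower (1.69 to 2.93). Below 2-fold on this scale, the myelin gene Mbp stood at 2.20 and 5.38 RPKM, 2.45-fold higher (1.98 to 3.04), and Gnb1l at 8.92 and 17.1 RPKM, 1.92-fold (1.64 to 2.25). The split of 3 higher and 12 lower was 4 and 6 under median ratio scaling and 4 and 9 under upper quartile scaling, and 127 genes passed when blank cells were read as 0, 46 higher and 81 lower. The calls of the TGF-beta and BMP, cardiac transcription factor and cell cycle lists were lost among genes with at least 50 reads in each library, the last at a median of −0.18, and those of the sarcomere (median 0.04, percentile 97.4), cardiac transcription factor (0.05, percentile 97.2) and RNA type and quality lists (−0.19, percentile 4.58) among genes listed in both Hey1-line libraries, where the Notch (0.07), skeletal muscle (0.10) and glycolysis (−0.15) lists lay outside the range instead. The Notch list holds the induced gene Hey1, and its other 14 members there had a median of 0.05 at percentile 94.8, inside the range.

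Induction of Hey2 was examined in the same way. Rassf8, an adaptor at epithelial junctions, was 3.33-fold higher in the induced library (1.88 to 6.34), at 1.4 and 4.67 RPKM. Mixl1, a homeobox gene of the primitive streak, was 2.72-fold lower (1.94 to 3.85), at 6.76 and 2.48 RPKM. It was also 1.56-fold lower (1.07 to 2.30) in the Hey1 line, at 4.37 and 2.80 RPKM. Between the uninduced lines it was only 1.55-fold higher in the Hey2 line (1.12 to 2.14). T and Eomes of its list, chosen after their values were seen, were at least 26.6-fold and 23.9-fold higher there. Why Mixl1 differed from them was not tested. The fibroblast and extracellular matrix, epicardial, pluripotency and interferon response lists were higher as groups.

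Of 19 fibroblast and extracellular matrix genes 18 were higher in the induced Hey2-line library, with a median of 0.26 at percentile 100 (range of random lists −0.10 to 0.11). The proteoglycan genes Dcn, 1.71-fold (1.07 to 2.80), and Bgn, 1.71-fold (1.06 to 2.87), and the collagen genes Col5a2, 1.37-fold (1.17 to 1.62), and Col1a1, 1.31-fold (1.21 to 1.42), were higher. Sparc was 1.10-fold higher (1.06 to 1.14). Of 5 epicardial genes 4 were higher (median 0.38, percentile 99.96). These were led by keratins, with Krt18 at 84.0 and 134 RPKM, 1.59-fold (1.46 to 1.74), Krt19 at 1.33-fold (1.18 to 1.5) and Krt8 at 1.31-fold (1.18 to 1.45). In the same libraries the sarcomere list, which stands for cardiomyocytes, had a median of 0.05 at percentile 95.8.

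Of 20 pluripotency genes 14 were higher after Hey2 induction (median 0.15, percentile 99.9). Tcfcp2l1 was 1.73-fold higher (1.39 to 2.17), Esrrb 1.58-fold (1.32 to 1.92) and Klf5 1.55-fold (1.15 to 2.10). By contrast the de novo methyltransferase gene Dnmt3b was 1.45-fold lower (1.36 to 1.54) and Pou5f1, which encodes Oct4, was 1.18-fold lower (1.08 to 1.30). All 6 interferon response genes were higher (median 0.27, percentile 99.7), with Ifit2 at 1.51-fold (1.03 to 2.27) and Bst2 at 1.24-fold (1.09 to 1.4). Of 11 epithelial-mesenchymal transition genes 8 were higher (median 0.16, percentile 98.9), with Mmp14 at 1.71-fold (1.17 to 2.55) and the tight junction gene Tjp1 at 1.24-fold (1.15 to 1.34).

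Altogether 5 of 10991 genes (0.0455%) differed by 2-fold or more on the log2(RPKM + 1) scale in the Hey2 line, 1 higher and 4 lower. This count lay within the range of 0 to 8 (mean 3.19) that read sets with equal expression gave. It leaves out genes blank in a library, Hey2 itself among them. Smaller differences were more than counting error gave, with a standard deviation over genes of 0.209 against 0.169. The 95% interval of the fold lay above 1 for 883 genes and below 1 for 729, of 10987 with recovered reads. Counting error alone would put up to 5% of such intervals off 1, so these counts are not numbers of changed genes. Besides Mixl1, the genes lower by 2-fold or more on this scale were Rpp21, 2.51-fold (1.31 to 4.88), and 2 without a known function. Below that size, the extracellular matrix gene Efemp1 was 2.26-fold higher (1.46 to 3.62), Lgals3bp 2.18-fold (1.44 to 3.40) and the chromatin regulator Arid5b 2.02-fold (1.54 to 2.70). The mitochondrial leucyl-tRNA synthetase gene Lars2 was 1.97-fold lower (1.83 to 2.12), at 66.7 and 33.8 RPKM, and the potassium channel subunit gene Kcnip1 2.25-fold lower (1.58 to 3.20). The split of 1 and 4 was 2 and 4 under upper quartile scaling, and 18 and 21 at a pseudocount of 0.1 RPKM. When blank cells were read as 0, 58 genes passed, 44 higher and 14 lower, the opposite balance. Longer genes were higher after Hey2 induction (Spearman's rho 0.230 across genes, which are not independent), and the epithelial-mesenchymal transition call was lost when this trend was removed. That call was lost in 5 settings in all, and among genes listed in both Hey2-line libraries 8 of its members were higher and 7 lower (median 0.00, percentile 55.1). The pluripotency call was lost among genes with a mean of at least 5 RPKM.

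The 2 inductions were then compared to see which differences the lines had in common. Both induced libraries had received doxycycline, so an effect of the drug cannot be told apart from one shared by Hey1 and Hey2. No gene passed 2-fold in both lines on the log2(RPKM + 1) scale. As plain ratios of RPKM a few did, among them Wdr38 and Vwa3a. At 1.5-fold, 3 genes were higher and 6 lower in both, where independent lists would share 0.273 and 1.53. Opposite ways, 1 gene was higher in the Hey1 line and lower in the Hey2 line, and 0 the reverse, where independent lists would share 0.346 and 1.21. At a ratio of 5 to 4, 29 genes were higher and 132 lower in both lines (20.3 and 81.6 for independent lists), and 43 and 73 went opposite ways in the same order (21.3 and 77.8). Wdr38 was among the higher ones, 2.65-fold in the Hey1 line and 2.47-fold (1.34 to 4.92) in the Hey2 line. Vwa3a was 3.12-fold lower (2.0 to 5.0) and 2.04-fold lower (1.51 to 2.76). Across genes the inductions barely correlated, with Pearson's r of 0.0447 (bootstrap over genes 0.0243 to 0.0672) and Spearman's rho of 0.0416. Among 4349 genes with at least 100 reads in each library r was 0.0683. Counting error holds such a correlation down in part, though r stayed low among these genes with more reads. Over all compared genes counting error alone gave a standard deviation of 0.174 of the 0.231 seen in the Hey1 induction and 0.169 of 0.209 in the Hey2 induction. The cultures of the 2 lines also differed without induction. The low r thus does not show that the 2 responses are unrelated. The difference between lines was nearly the same with and without induction (r = 0.963, rho = 0.952). There counting error was small beside the differences, at 0.178 of 1.09 between the uninduced libraries.

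**Figure D2:**
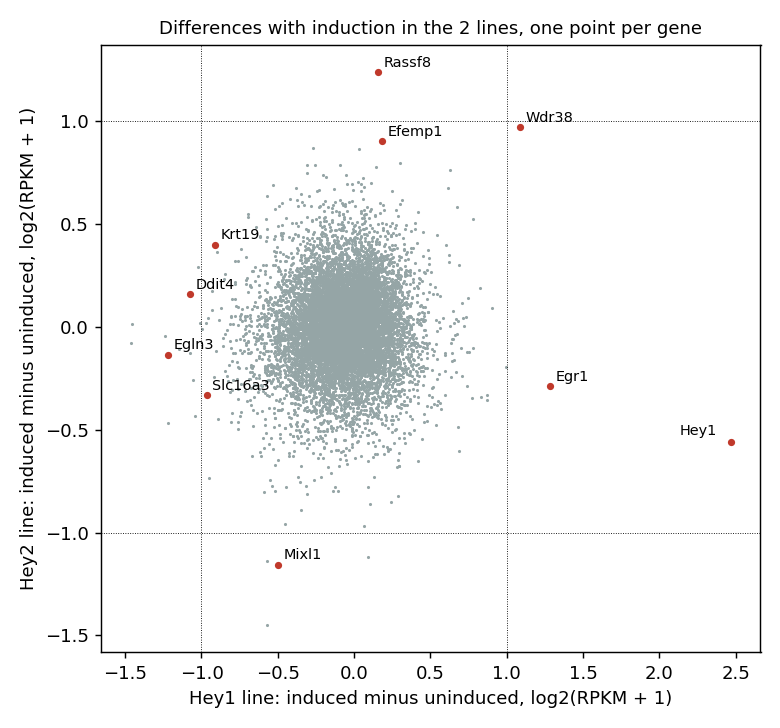
Difference of log2(RPKM + 1), induced minus uninduced, in the Hey1 line (x axis) and the Hey2 line (y axis), with 1 point per gene for 10991 genes and dotted lines at 2-fold. Hey1 lies far to the right at 2.47 on the Hey1-line axis, and no gene lies past 2-fold on both axes.

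A limma model over the 4 libraries, with the 2 lines as the replicates of induction, called 57 genes at a Benjamini-Hochberg adjusted p under 0.05, 7 higher and 50 lower. Unadjusted, 839 of 10991 genes lay under 0.05, where 549.55 would by chance. The p-values rest on 1 residual degree of freedom and on variances shared among genes. The shared part weighed as 164.9 degrees of freedom, so a gene's own disagreement between the lines counted little. The lines thus hardly acted as replicates, and on simulated data the model called too many unchanged genes. Under median ratio scaling the split was 5 and 11, under upper quartile scaling 10 and 17, and without the line term 0 genes were called by limma and 1 at an unadjusted p under 0.05. Without that term the large difference between lines enters the residual variance, so hardly any call was possible. Of the calls, 55 went the same way in both lines, but only 9 reached 1.5-fold in both, and Hey1 was called although it went opposite ways. The limma difference of Wdr38 was 1.03 (SE 0.157, Benjamini-Hochberg adjusted p = 2.33e-06, higher in 2 of 2 lines). Lars2 (−0.70, SE 0.126, limma Benjamini-Hochberg adjusted p = 0.000170), Vwa3a (−0.84, SE 0.153, adjusted p = 0.000206) and Mixl1 (−0.83, SE 0.159, adjusted p = 0.000647) were lower in both lines. Entrez100628584 and Mir682, with recovered lengths of 174 and 192 bases, had a smaller limma adjusted p than Wdr38. Mir5114 (122 bases) and Mir1902 (160 bases) were called too. How reads were assigned to such short genes is not given, so these calls are uncertain. Lars2, Mixl1 and Entrez100628584 moved alike, by −0.45, −0.50 and −0.57 in the Hey1 line and −0.96, −1.16 and −1.45 in the Hey2 line. What they share was not tested.

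Of the members of the fixed lists, limma called 4 over all genes and 16 adjusted over the list alone, 4 higher and 12 lower, with Pgk1 called in 2 lists. In the hypoxia list there was 1 call over all genes and 4 adjusted over the list alone (Adm, Bnip3, Egln3 and Ndrg1, all lower). In the glycolysis list these numbers were 1 and 3 (Ldha, Pgam1 and Pgk1, all lower), and in the immediate early list 0 and 3 with a higher mean over the lines (Egr1, Fos and Junb). Of these, Egr1 went opposite ways, at 1.28 in the Hey1 line and −0.29 in the Hey2 line. The RNA type and quality list had 0 and 2, and the cell cycle (E2f1), integrated stress response (Ddit4) and housekeeping (Pgk1) lists 0 and 1 each. Ddit4 went opposite ways too, at −1.07 and 0.16. The Notch list (Hey1) and the mesoderm list (Mixl1) had 1 call either way. Called members are named here after their values were seen.

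The largest differences lay between the lines themselves. Without induction, sarcomere genes were far lower in the Hey2 line than in the Hey1 line, and pluripotency and cell cycle genes far higher. The atrial light chain gene Myl4 stood at 4940 RPKM in the Hey1 line and 138 RPKM in the Hey2 line, 35.9-fold lower (33.3 to 38.7). Pou5f1 stood at 9.93 and 98.1 RPKM, 9.88-fold higher (8.06 to 12.2), and Dnmt3b at 0.521 and 71.4 RPKM, 137-fold higher (85.4 to 236).

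All 27 sarcomere genes were lower in the uninduced Hey2 line, with a median difference of −3.56. Cardiac actin (Actc1) was 22.4-fold lower (21.3 to 23.5), Tnnc1 31.5-fold (27.3 to 36.4) and Myl7 26.4-fold (24.2 to 28.8). Of 21 cardiac transcription factor genes 20 were lower (median −1.88), with Nkx2-5 17.7-fold lower (12 to 27.4) and Tbx20 15.9-fold (13.9 to 18.4). Calcium handling and ion channel genes had a median of −2.21 (21 of 24 lower), with the pacemaker channel gene Hcn4 45.5-fold lower (27.4 to 81.6). Atrial-associated genes had a median of −2.46 (11 of 12 lower) and ventricular-associated genes of −2.28 (11 of 11 lower), with Myl2 14.8-fold lower (13.7 to 16.0). Oxidative phosphorylation genes (24 of 24 lower, median −1.56), fatty acid oxidation genes (18 of 18, median −1.60), skeletal muscle genes (9 of 10, median −1.98) and integrated stress response genes (17 of 21, median −1.15) were lower too. Examples were Cox4i1, 4.67-fold (4.27 to 5.12), Cpt1b, 6.48-fold (4.57 to 9.42), Ckm, 37.5-fold (18 to 94), and Atf5, 17.3-fold (11.8 to 26.5).

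Of 20 pluripotency genes 19 were higher in the uninduced Hey2 line (median 2.20), among them Lin28 at 61.2-fold (40.9 to 95.9), Tdgf1 at 40.7-fold (25.8 to 68.1) and Nanog at 13.4-fold (9.06 to 20.5). All 29 cell cycle genes were higher (median 2.31), with Top2a at 12.2-fold (10.8 to 13.9) and Ccnb1 at 9.88-fold (7.17 to 13.9). All 15 cholesterol synthesis genes were higher (median 1.62). Epicardial genes, again mainly keratins, had a median of 2.53 (5 of 5 higher, Krt8 at 12.6-fold, 9.55 to 16.9). Wnt and Fgf genes had a median of 1.03 (14 of 18 higher, Tcf7 at 29.2-fold, 17.2 to 54.1), neural genes of 1.34 (4 of 6 higher, Stmn2 at 23.1-fold, 14.7 to 38.3), and endothelial genes of 1.13 (5 of 5 higher, Flt1 at 12-fold, 6.87 to 22.5). Endoderm genes went both ways (median 1.03, 4 higher and 4 lower), with Lama1 62.4-fold higher (44.2 to 91.0) and the fetal liver and yolk sac gene Afp 41.3-fold lower (25.6 to 71.2).

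**Figure D3:**
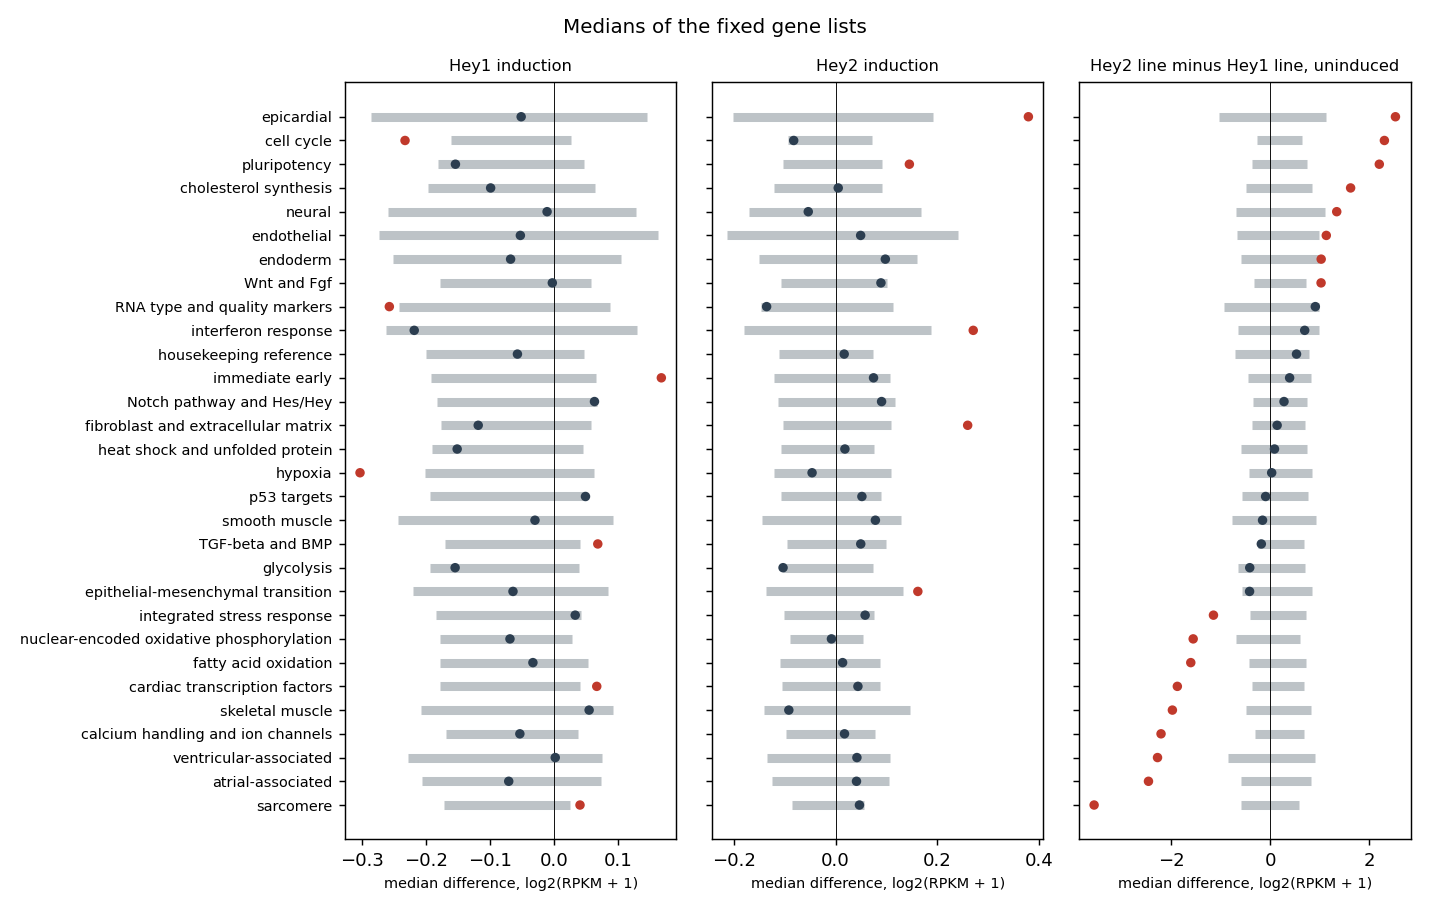
Median log2 difference of each gene list for Hey1 induction, Hey2 induction and the uninduced Hey2 line minus the uninduced Hey1 line, as points, with the 95% range of random lists as grey bars and lists outside it in red. Medians for the inductions lay between −0.30 and 0.38, whereas between the lines the sarcomere list differed by −3.56 and the cell cycle list by 2.31.

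Between the uninduced libraries 3606 genes (32.8%) differed by 2-fold or more, 2167 higher and 1439 lower in the Hey2 line, against a mean of 2.89 genes from counting error. Between the induced libraries 3866 genes (35.2%) did, 2509 higher and 1357 lower, and 8 lists lay above and 10 below the range of random lists. For the uninduced libraries 8 lay above and 9 below. Of these 2 comparisons, only that of the induced libraries had TGF-beta and BMP genes (median −0.31, percentile 0.84) and interferon response genes (median 1.09, percentile 97.52) outside, and only that of the uninduced ones neural genes, a difference that was not tested. Median ratio scaling shifted the median of all genes from 0.20 to 0.02 (uninduced) and from 0.27 to 0.01 (induced), and turned the splits into 1627 higher and 1768 lower, and 1750 and 1882. The endothelial call was lost with blank cells as 0, and the endoderm call at a pseudocount of 5 RPKM. No library of the same line and treatment measures how much of this arises between cultures of 1 line.

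The remaining lists lay inside the range of random lists for the inductions and for the uninduced lines. In the Hey1 induction their medians were 0.06 for Notch, −0.05 for calcium handling and ion channels, −0.07 for atrial, 0.00 for ventricular, −0.15 for pluripotency, −0.05 for endothelial, −0.03 for smooth muscle, −0.12 for extracellular matrix, −0.05 for epicardial, −0.07 for endoderm, −0.01 for neural, 0.05 for skeletal muscle, −0.06 for epithelial-mesenchymal transition, −0.00 for Wnt and Fgf, 0.05 for p53, 0.03 for stress response, −0.07 for oxidative phosphorylation, −0.03 for fatty acid oxidation, −0.15 for glycolysis, −0.15 for heat shock, −0.10 for cholesterol, −0.22 for interferon and −0.06 for housekeeping genes. In the Hey2 induction they were 0.09 for Notch, 0.04 for cardiac transcription factors, 0.02 for calcium handling, 0.04 for atrial and for ventricular, 0.05 for endothelial, 0.08 for smooth muscle, 0.10 for endoderm, −0.05 for neural, −0.09 for skeletal muscle, 0.05 for TGF-beta and BMP, 0.09 for Wnt and Fgf, −0.08 for cell cycle, 0.05 for p53, 0.06 for stress response, −0.01 for oxidative phosphorylation, 0.01 for fatty acid oxidation, −0.10 for glycolysis, −0.05 for hypoxia, 0.07 for immediate early, 0.02 for heat shock, 0.01 for cholesterol, 0.02 for housekeeping genes and −0.14 for RNA type and quality markers. Between the uninduced lines they were 0.28 for Notch, −0.15 for smooth muscle, 0.14 for extracellular matrix, −0.18 for TGF-beta and BMP, −0.42 for epithelial-mesenchymal transition, −0.09 for p53, −0.41 for glycolysis, 0.03 for hypoxia, 0.39 for immediate early, 0.09 for heat shock, 0.70 for interferon, 0.53 for housekeeping and 0.91 for RNA quality genes. Of the blood list 0 of 17 genes and of the mesoderm list 2 of 18 could be compared over all libraries, and 0 of 13 mitochondrially encoded genes were matched. By chance 1.5 of 30 lists per comparison would lie outside the range.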

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

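The tests of counting error and gene length were fixed before their list-level results were seen, and the tests of scaling, cell shares, other culture differences and other cells were chosen after. The patterns weighed were themselves picked from 30 lists in 3 comparisons after their medians were seen. No biological explanation is separated from the single culture per group.

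Only lists outside the range of random lists in at least 1 induction were considered here. Their medians that went opposite ways in the lines differed, Hey2 line minus Hey1 line, by 0.30 for pluripotency genes, 0.38 for fibroblast and extracellular matrix genes, 0.43 for epicardial genes, 0.23 for epithelial-mesenchymal transition genes and 0.49 for interferon response genes. Other lists inside the range in both inductions also had medians of opposite sign. Among the genes picked by the naming rules, those with opposite differences beyond counting error in both lines were Hey1 (−3.03), Egr1 (−1.57), Zbtb8os (−1.29), Gnb1l (−1.22) and Krt19 (1.31). Krt19 was 2.21-fold lower after induction in the Hey1 line and 1.33-fold higher in the Hey2 line. With 1 library per group these differences between lines were not tested. The inductions also ran in cultures that already differed without induction, by medians of −3.56 for sarcomere and 2.20 for pluripotency genes (Hey2 line minus Hey1 line). A difference between Hey1 and Hey2 therefore cannot be told apart from one between lines or cultures, which more libraries of these cultures would not change.

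In the uninduced Hey2-line library sarcomere genes were lower and pluripotency genes higher than in the Hey1 line. Median ratio scaling moved the median of all genes only from 0.20 to 0.02 and left the pluripotency median at 2.05. Scaling by a few abundant transcripts is thus too small a shift to give that median. The range of random lists could not test this, since 1 factor per library moves all genes alike. A lower share of cardiomyocytes, with more undifferentiated, dividing or other cells, may account for it, and the cell cycle median of 2.31 goes with that but was seen before the explanation was written. All 27 sarcomere genes were lower, from 2.08-fold to 45.5-fold, and all 27 again between the induced libraries (median −3.76), which both fewer cardiomyocytes and cardiomyocytes that differ might give. What else sets the lines apart was not tested.

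Hypoxia genes were lower in the induced Hey1-line library, with a median of −0.30. Counting error is argued against, since the 95% range of medians from read sets with equal expression reached down to −0.086 and 0 of 1000 were as low as observed. With the gene length trend removed the median was −0.30, but this removal could hardly have changed it. The trend was weak in this comparison (Spearman's rho 0.051), and the hypoxia genes had a median length of 2890 bases against 2894 for compared genes. In the Hey2 line the median was −0.046, which both a Hey1-specific effect and another difference between the 2 cultures might give, so these cannot be told apart. RNA type and quality markers were lower in the same Hey1-line comparison, with a median of −0.26 and 7 of 9 lower, so a difference in the RNA of these libraries is left open too.

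Fibroblast and extracellular matrix genes were higher in the induced Hey2-line library, with a median of 0.26. Counting error, whose upper limit was 0.058 (0 of 1000 as high), and the length trend, whose removal left 0.23, are argued against. A larger share of other cells in that culture could raise these genes. The sarcomere median of 0.047, which it would lower, lies inside the range of random lists. So do the endothelial (0.05, percentile 62.6) and smooth muscle (0.08, percentile 91.5) medians, which only some kinds of other cells would raise. None of these has the value that was predicted, and none lies where it would be excluded. Of the further lists that stand for other cells, epicardial (0.38, percentile 99.96) and pluripotency genes (0.15, percentile 99.9) lay above the range. Endoderm (0.10), neural (−0.05) and skeletal muscle genes (−0.09) lay inside it. With 1 library per group a larger share of other cells cannot be told apart from an effect of Hey2 or of doxycycline.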

How the results depend on the processing

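Blank cells read as 0, at least 50 reads per library, length matching or removal, the Notch list without Hey1, and genes listed in both libraries of 1 line were tests chosen after the data were seen. Counts past 2-fold depended on the pseudocount, size rule and set of genes. The Hey1 count of 15 was 82 and 4 at pseudocounts of 0.1 and 5, 271 and 1 at 1.5-fold and 3-fold, 127 with blanks as 0, 5 with at least 50 reads and 3945 against the other line's control. The Hey2 count of 5 was 39, 1, 136, 0, 58, 1 and 3509 in the same order, and 14 among genes listed in both Hey2-line libraries. The count of 3606 between uninduced lines was 1716 at a pseudocount of 5, 6170 and 1458 at 1.5-fold and 3-fold, and 2040 with at least 50 reads. The count of 3866 between induced lines was 1851, 6389, 1627 and 2225. The 0 genes past 2-fold in both lines became 3 at a pseudocount of 0.1, 1 under upper quartile scaling, 9 at 1.5-fold and 4 with blanks as 0. The 57 limma calls became 14 and 1 at pseudocounts of 0.1 and 5, 16 and 27 under median ratio and upper quartile scaling, 35 without the trend, 2 with blanks as 0, 21 with at least 50 reads, and 0 without the line term. Each library was also left out in turn, in a model without the line term where the lone library is assumed to vary like the other group. Without that term the difference between lines enters the residual variance. Its standard deviation over genes was 1.09, against 0.231 and 0.209 for the inductions. Models without the line term could thus hardly call a gene, and they do not test the 57 calls. The Hey1 difference of 2.47 was 1.24 at a pseudocount of 5. Mir5114 reversed in the Hey2 induction under upper quartile scaling, from −0.08 to 0.016. Where not given by construction, the cause was not tested. Of the list medians, 327 of 349 kept their call or lack of one in the Hey1 induction (9 lost and 13 gained a call), 332 of 351 in the Hey2 induction (6 and 13) and 312 of 320 between lines (3 and 5), and 0 reversed. Calls were lost in the Hey2 induction for the epithelial-mesenchymal transition list (5 settings) and the pluripotency list (mean of at least 5 RPKM), and between lines for the endoderm and endothelial lists. Genes near the listing floor of 10 or 5 reads are limited by depth.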

Other observations

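Genes listed in both libraries of the Hey2 line, a set chosen after the data were seen, brought in mesoderm and interferon genes that are mostly blank in the Hey1 line. Of 10 mesoderm and cardiac progenitor genes 9 were lower after Hey2 induction, with a median of −0.41 at percentile 0 of random lists (range −0.15 to 0.15). Eomes, a T-box gene of the primitive streak, stood at 5.86 and 2.97 RPKM, 1.97-fold lower (1.59 to 2.45), and the Nodal antagonist gene Cer1 at 4.89 and 2.60 RPKM, 1.88-fold lower (1.23 to 2.87). Mixl1 was 2.72-fold lower, Wnt3 1.60-fold (1.06 to 2.42) and Kdr 1.57-fold (1.04 to 2.37). Fgf8 lay 1.26-fold lower, within counting error (0.973 to 1.64), and Pdgfra was the exception, 1.09-fold higher (0.855 to 1.39). In the same set 13 of 14 interferon response genes were higher, with a median of 0.35 at percentile 100. Oasl2 stood at 5.93 and 10.2 RPKM, 1.72-fold higher (1.38 to 2.16). The epithelial-mesenchymal transition list lay inside the range here, with a median of 0.00 at percentile 55.1.

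The next genes were chosen after their values were seen. Ldha and Pgk1 belong to the glycolysis list but do not stand for it as a whole. Ldha, which makes lactate from pyruvate, was 1.32-fold lower in the Hey1 line (1.23 to 1.41) and 1.52-fold lower in the Hey2 line (1.44 to 1.61), at 140 and 106 RPKM and at 215 and 141 RPKM. The lactate exporter gene Slc16a3 was 2.03-fold lower (1.74 to 2.36) and 1.27-fold lower (1.14 to 1.41). Pgk1 was 1.37-fold (1.28 to 1.46) and 1.26-fold (1.18 to 1.35) lower. Glycolysis genes as a list lay at −0.15 (percentile 7.73) and −0.10 (percentile 2.5), inside the range in both lines, but at percentile 2.46 and below it among genes listed in both Hey1-line libraries.

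Of genes blank in both libraries of 1 line and listed in both of the other, 1845 were blank in the Hey1 line and 81 in the Hey2 line, where the listing floors of 10 and 5 reads also differ. Of 18 mesoderm genes 10 were blank only in the Hey1 line, among them Eomes, at least 23.9-fold higher in the uninduced Hey2 line, and Fgf8, at least 13.3-fold. In the authors' deposited table the fold of Hey1 in the Hey1 line was 11.7, the highest of 11917, and that of Egln3 was −3.48, the lowest. Of the folds in the authors' deposited table, 31 of 11917 were 2 or more and 110 were −2 or less in the Hey1 line, against 93 and 214 of 14053 in the Hey2 line. That table has no pseudocount or minimum mean and reaches down to the lower floor in the Hey2 line.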
